A study of Mus musculus with 8 samples.

How the data were processed

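The series holds total RNA from retinae of wild-type, Mef2d knockout and Crx knockout mice at postnatal day 11. Per the labels, ribosomal RNA was removed by hybridisation, strand-specific libraries were made by the dUTP method, and 49 bp reads were taken on a HiSeq 2000, paired-end for the Mef2d knockouts and their wild types and single-end for the Crx knockouts and theirs. The submitters' processing notes name BWA 0.6.2 and the mouse genome build mm9. The deposited unit is a signal, the density of reads over the exons of each gene, and how the authors scaled it is not given in the sources used here. Whether the authors' counting used the strand or shared reads between copies of a gene is also not given. Reads that fit more than 1 copy of a gene can therefore shift between copies, and genes with near-identical copies are treated as uncertain.

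Each of the 2 tables held 27120 features in 4 libraries. The 1558 features of ribosomal RNA repeats were left out, which left 25562 genes. Of these, 22521 matched a RefSeq gene identifier of the GRCm38.p6 table, used only for current symbols and for transcript lengths (17024 genes). Coordinates are those of the deposited tables, in mm9. No genome sequence of that build was used here.

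The deposited tables give no read totals. For genes with 1 short transcript of known length, the value of 1 read was taken from the commonest low density times length. With that step, low values lay within 0.1 read of a whole number in 63.7% to 69.2% of cases. Evenly spread values would give 20%. The step was picked from these same values, so a share above 20% does not by itself show steps of whole reads. Over the genes with a known length this gave estimates of 38.7 to 41.7 M exonic reads per library in the Mef2d table and 60.0 to 66.3 M in the Crx table. The share was too low to recover counts, so a count model was not used. One read in a transcript of 2000 bp corresponds to a density of about 0.00211 to 0.00221 in the Mef2d table and 0.00131 to 0.00132 in the Crx table.

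Genes were kept where the mean density over the 4 libraries of a table reached its 25th percentile among genes above 0, a density of 0.0378 in the Mef2d table (15063 genes) and 0.032 in the Crx table (15601 genes). Densities were taken as log2(density + pseudocount), with a pseudocount of 0.0189 and 0.016, so that fold changes of low genes are understated. Each table was fitted alone with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend, residual degrees of freedom 2, prior degrees of freedom 7.34 and 4.23), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genotype was the only term. Gene lists with at least 3 tested members (23 in each comparison) were tested with camera in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. No list was called by camera with an estimated correlation in either comparison (smallest adjusted p 0.311 for Mef2d and 0.391 for Crx, with 2 lists in each below 0.05 before adjustment), while fry called 1 and 8. In the Mef2d comparison fry called the muscle list alone. In the Crx comparison it called the photoreceptor transcription factors up and did not call the microglia, pigment epithelium and activity-dependent lists. The lists cover rod and cone phototransduction, outer segment and cilium, photoreceptor synapse, photoreceptor transcription factors, retinoid and photoreceptor maintenance, the MEF2 family, gliosis, bipolar, amacrine, horizontal, ganglion and Müller cells, cell cycle, retinal progenitors, microglia, vessels, pigment epithelium, lens, blood, muscle, activity-dependent genes, and apoptosis with p53. The targeted genes are in none of them.

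Calls of the 2 knockouts were compared with Fisher's exact test, two-sided, over the 14891 genes tested in both tables, adjusted over the 4 pairs of directions. The tables share no wild-type library. The difference of effects was tested in a joint limma fit of the 8 libraries with 1 mean per group, so that each effect is taken within its own table. Calls by chromosome were compared with Fisher's exact test, adjusted over the 8 tests made.

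The groups, tests, lists, most alternatives and the rule for named genes were set before the data were examined. The rule took Mef2d and Crx, the 7 largest rises and 7 largest falls among called genes with a mean density of at least 1.59 (Mef2d) or 1.65 (Crx) and knockout libraries outside the wild-type range, the members of each list with the smallest adjusted p (up to 3 for the photoreceptor and other central lists, 1 for the rest), 5 genes called in both comparisons in the same direction and 3 in opposite directions, and the 3 largest differences of effect on each side. Rhodopsin, Nrl, Otx2, Gnb3, Gngt2, Cngb3 and Ccdc136 were added after their values were seen, as were other list members printed with a fold change alone. Some genes that the rule takes are not reported here.

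The alternatives were smaller and larger pseudocounts, no filter and a stricter one, median-of-ratios and quantile scaling, limma without trend and with robust priors, a minimum fold of 1.5, a term for the replicate of each sex, camera with an estimated correlation, fry, and each library left out in turn. Leaving out a library leaves 1 sample in that group, and the lone sample is assumed to vary like the others. Added after the data were seen were the counts without the chromosome of the targeted gene, without the sex chromosomes, and at a mean density of at least 1.

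The tests were tested on simulated data. With gene spreads drawn from the fitted prior, limma recovered 87.9% of genes changed by 1 on the log2 scale and 100% of those changed by 2 in the Mef2d design, 74.7% and 97.9% in the Crx design, and 80.1% and 97.4% for the difference of effects, and unchanged genes made up 3.16%, 3.43% and 4.21% of the calls. A simulation run first, with each gene's spread as fitted, gave higher shares of unchanged genes among the calls, 13.6% in the Mef2d design and 12.5% in the Crx design, above the nominal 5%. The simulation with spreads from the prior was added after that result, and the share of false calls in the real data was not measured, so it can lie above 5%. In both designs a list lowered by 1 was called and 0 unchanged lists were. Noise was drawn independently for each gene, so this does not measure false list calls where the genes of a list vary together. Sex labels matched Xist and 4 Y-linked genes in 8 of 8 libraries. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.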

Results

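Total RNA was sequenced from the retina of mice at postnatal day 11, when rods and cones are still forming their outer segments. The 8 libraries fall into 4 groups of 2 animals. Knockouts of Mef2d, a MADS-box transcription factor, were set against wild-type littermates, and knockouts of Crx, the homeobox factor of photoreceptors, against wild types of their own. Each group held 1 male and 1 female, and each library held both retinae of 1 animal, so the replicates are separate animals. Values are exon densities per gene in 2 tables, 1 per knockout with its wild types; whether both were scaled alike is not given in the sources used here, and every test of a knockout was made within its table. The low densities gave an estimated 38.7 to 41.7 M exonic reads per library in the Mef2d table and 60.0 to 66.3 M in the Crx table. These estimates cover the genes with a known transcript length, and in the paired-end Mef2d table the unit may be a read pair. The series title names the role of MEF2D in photoreceptor development, and the comparisons ask which retinal transcripts depend on each factor and how far the affected genes coincide.

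The targeted genes were lower in the libraries labelled as their knockouts. Mef2d (GeneID 17261, chr3:87946317–87973089, mm9) had densities of 2.78 and 2.90 in the wild types and 1.71 and 1.85 in the Mef2d knockouts, a log2 change of −0.67 ± 0.09 (SE, n = 2 per group, limma adjusted p = 0.00258). Crx (GeneID 12951, chr7:16451298–16465243, mm9) had 144 and 148 in its wild types and 64.7 and 66.0 in the Crx knockouts, a log2 change of −1.16 ± 0.11 (n = 2 per group, limma adjusted p = 0.00109). Which exons were removed is not given in the sources used here, and reads from the remaining exons still enter these densities. Crx did not pass the threshold in the Mef2d knockout (log2 −0.02 ± 0.09, limma adjusted p = 0.955), nor did Mef2d in the Crx knockout (−0.10 ± 0.09, adjusted p = 0.489).

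In the Mef2d knockout retina a small set of photoreceptor genes fell steeply, while most genes of the rod, outer segment and synapse lists did not pass the threshold. Cone arrestin Arr3, which shuts off cone opsins, dropped from a density of 7.72 ± 1.54 to 0.0209 ± 0.0126 (SD, n = 2). Guca1b, an activator of the guanylate cyclase that restores cGMP after light, dropped from 6.21 ± 1.08 to 0.246 ± 0.0547, and the actin-bundling protein Fscn2 of the outer segment from 5.37 ± 0.00785 to 0.514 ± 0.0451. Rhodopsin, the rod visual pigment, stood at 611 ± 30.2 in wild type and 518 ± 44.9 in the knockout and did not pass the threshold (log2 −0.24, limma adjusted p = 0.385). Of 15063 genes tested with limma, 328 rose and 293 fell at an adjusted p below 0.05, and 76 of the rises and 124 of the falls reached 2-fold. With libraries rescaled by the median of ratios the split was 248 up and 346 down. The number of calls was 291 without the wild type 1 library and 364 without wild type 2.

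Among called genes with a mean density of at least 1.59, the 7 largest falls and 7 largest rises were taken by size of change. The log2 change was −7.72 ± 0.23 for Pdzph1 (GeneID 69239) and −7.63 ± 0.22 for Arr3 (GeneID 170735, chrX:97800895–97813832, mm9). The phospholipase A2 receptor Pla2r1 (GeneID 18779, chr2:60257096–60391318) had −4.60 ± 0.12, Guca1b (GeneID 107477, chr17:47522342–47529916) −4.56 ± 0.16 and Fscn2 (GeneID 238021, chr11:120222848–120229485) −3.34 ± 0.10, each with n = 2 per group and a limma adjusted p of at most 4.58e-07. The ribosomal protein genes Rps3a1 (−5.38 ± 0.23) and Rpl34 (−5.23 ± 0.23) completed the falls; both lie on chromosome 3, as does Mef2d, and both have near-identical copies elsewhere in the genome, so their values are uncertain. The histone pseudogene H2af-ps2, on chromosome 13 and likewise uncertain because of near-identical copies, showed the largest rise, from 0.111 ± 0.0102 to 18.6 ± 0.923 (log2 7.16 ± 0.10). The other large rises were smaller. Collagen gene Col26a1 rose by 2.07 ± 0.12, calmodulin-like Calml4 by 2.04 ± 0.11, the secreted protein gene Scube3 by 1.41 ± 0.10, the polo-like kinase gene Plk5 by 1.36 ± 0.09, Proser2 by 1.32 ± 0.08 and the potassium channel gene Kcnn1 by 1.18 ± 0.09, with limma adjusted p between 9.09e-06 and 5.31e-05.

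Camera called the cone and rod phototransduction lists down in the Mef2d knockout, while fry did not (adjusted p = 0.0574 and 0.109). In the cone list 7 of 13 genes fell and none rose over all genes tested, and 9 fell when adjusted over the list alone (median log2 −0.43, camera adjusted p = 3.45e-17; adjusted p = 0.311 with an estimated correlation). Besides Arr3, the falls included Pde6h, the inhibitory subunit of cone phosphodiesterase (−2.82 ± 0.10), the potassium channel subunit gene Kcne2 (−1.17 ± 0.13) and the short-wavelength opsin Opn1sw (−0.94). In the rod list 6 of 19 genes fell and 0 rose, or 8 and 0 when adjusted over the list alone (median −0.24, camera adjusted p = 1.87e-12; adjusted p = 0.311 with an estimated correlation). Guca1a, the neighbour and paralogue of Guca1b, fell (−1.21 ± 0.09), as did the rod transducin subunit Gngt1 (−1.02 ± 0.09). The retinoid and maintenance list was called down by camera (adjusted p = 0.0102; adjusted p = 0.773 with an estimated correlation) with a mean of −0.55 but a median of 0.04, which became −0.01 under median-of-ratios scaling, and the call was lost with quantile normalization (camera adjusted p = 0.0560). Of its 14 genes 3 fell and 1 rose, or 4 and 1 when adjusted over the list alone. The falls were those of Pla2r1, the hexokinase Hk2 that begins glycolysis (−2.83 ± 0.15) and the photoreceptor potassium channel subunit Kcnv2 (−1.20 ± 0.07), while Crb1 of the outer limiting membrane rose by 0.59.

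Other photoreceptor lists were not called in the Mef2d knockout, though single members moved. In the outer segment and cilium list 2 of 19 genes rose and 2 fell, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.893). Fscn2 and the protocadherin Pcdh15 (−2.88 ± 0.11) fell, and the photoreceptor cadherin Cdhr1 rose by 0.48 ± 0.08. In the photoreceptor synapse list the calcium channel subunits Cacna1f (0.37 ± 0.08) and Cacna2d4 (0.31 ± 0.07) were the 2 members of 15 that rose, with 0 falls, or 4 rises and 3 falls when adjusted over the list alone (camera adjusted p = 0.893). The synaptic glutamate transporter Slc17a7 stood at −0.34 ± 0.08 (limma adjusted p = 0.0566) and passed the threshold with median-of-ratios scaling (0.0284) and quantile normalization (0.0351). Median-of-ratios scaling ended the Cacna2d4 call (limma adjusted p = 0.119), and the synapse list then had 1 rise and 1 fall. Among 14 photoreceptor transcription factors the nuclear receptor Esrrb fell by 0.98 ± 0.11 and 0 rose, or 2 up and 2 down when adjusted over the list alone (camera adjusted p = 0.893), with Prdm1 at 0.34 (limma adjusted p = 0.103) and Thrb at −0.28 (0.113). The calls of Cdhr1, Cacna1f and Cacna2d4 were lost in limma on leaving out single libraries, with adjusted p of up to 0.0956, 0.223 and 0.236.

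Microglial transcripts were higher in the Mef2d knockout. Fry gave an adjusted p of 0.0574 for the microglia list, 0.0286 for the muscle list and 0.137 for the bipolar list. Of 15 microglia markers 8 rose and 0 fell, or 13 and 0 when adjusted over the list alone (median log2 0.55, camera adjusted p = 1.01e-11; adjusted p = 0.311 with an estimated correlation). The complement gene C1qc went from 1.75 ± 0.0938 to 2.94 ± 0.173 (SD, n = 2), and Aif1 and P2ry12 rose by 0.88 and 0.71 on the log2 scale. P2ry12 lies on chromosome 3, as does Mef2d. Skeletal muscle genes were lower as a list (3 of 7 fell, 0 rose, 4 and 0 when adjusted over the list alone, median −0.76, camera adjusted p = 2.80e-07; adjusted p = 0.311 with an estimated correlation), led by the muscle form of glycogen phosphorylase, Pygm (−1.66 ± 0.10). In the bipolar cell list 2 of 18 genes fell and 0 rose, or 4 and 0 when adjusted over the list alone (median −0.11, camera adjusted p = 3.79e-05; adjusted p = 0.311 with an estimated correlation), with Lrtm1 at −1.20 ± 0.11.

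Of the lens and pigment epithelium markers, 0 genes passed the threshold in the Mef2d knockout. The 13 lens genes had a median of 1.45 (1 rise when adjusted over the list alone, camera adjusted p = 0.00141; adjusted p = 0.773 with an estimated correlation), and the crystallin Cryba2 stood at 1.45 ± 0.35 (limma adjusted p = 0.0516; 0.0278 without wild type 1 and 0.0313 without Mef2d knockout 1). The summed density of lens genes was 0.999 and 0.892 in the wild types, 1.06 in Mef2d knockout 1 and 5.18 in Mef2d knockout 2, and without that last library the lens median was 0 (camera adjusted p = 0.552). The 12 pigment epithelium genes had a median of 0.23, with 0 past the threshold also when adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.773 with an estimated correlation). That call was lost in camera without wild type 1 (adjusted p = 0.200) and without Mef2d knockout 2 (0.794).

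The remaining lists were not called in the Mef2d knockout with all 4 libraries. Camera adjusted p was 0.0818 for amacrine, 0.0936 for ganglion cell, 0.161 for Müller glia, 0.199 for vascular, 0.468 for horizontal cell, 0.538 for cell cycle, 0.538 for retinal progenitor, 0.616 for blood, 0.721 for the other MEF2 genes, 0.893 for gliosis and 0.893 for apoptosis and p53 genes. Without wild type 2, camera called the amacrine (adjusted p = 0.0207), ganglion cell (0.0113), Müller glia (0.0111) and vascular (0.0443) lists down, with medians of −0.11, −0.10, −0.12 and −0.14, and without Mef2d knockout 1 the amacrine and vascular lists (0.0186 for both). With all libraries, in these lists 1 horizontal cell gene and 1 cell cycle gene fell, over all genes tested and when adjusted over the list alone, and 1 gliosis gene rose and 1 fell when adjusted over the list alone; the other lists had 0 genes past the limma threshold either way. The calcium-binding Calb1 of horizontal cells was the only one of its 5 genes past the threshold (−0.42 ± 0.10, limma adjusted p = 0.0494), and it lost that call without wild type 1 (adjusted p = 0.454). The cyclin gene Ccna2, on chromosome 3, fell by 0.85 ± 0.11. Among activity-dependent genes Egr1 (1.64 ± 0.17) and Junb (0.45) rose of 8 tested, the same count as when adjusted over the list alone, and the list itself had a camera adjusted p of 0.184 (0.0103 without a filter). Mef2a (−0.05 ± 0.10), Mef2b (−0.15 ± 0.21) and Mef2c (0.12 ± 0.14) did not pass the threshold. Named members of the other lists that also did not pass were Fgf2 (−0.62), Nefh (−0.34), Glul (−0.24), Gad1 (−0.21), Rgs5 (−0.17), Hba-a1 (−0.08), Mdm2 (0.18), Stat3 (0.23), Rdh5 (0.39), Lcn2 (0.63) and Sfrp2 (0.74), with limma adjusted p from 0.0967 to 0.757. With a term for the replicate of each sex, Fgf2, Nefh, Lcn2 and Sfrp2 passed, as did Prdm1, Slc17a7 and Cryba2 (limma adjusted p from 0.00274 to 0.0413). In limma Fgf2 (adjusted p = 0.0179) and Sfrp2 (0.0389) passed without Mef2d knockout 2, and Lcn2 (0.00990) without Mef2d knockout 1.

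**Figure D1:**
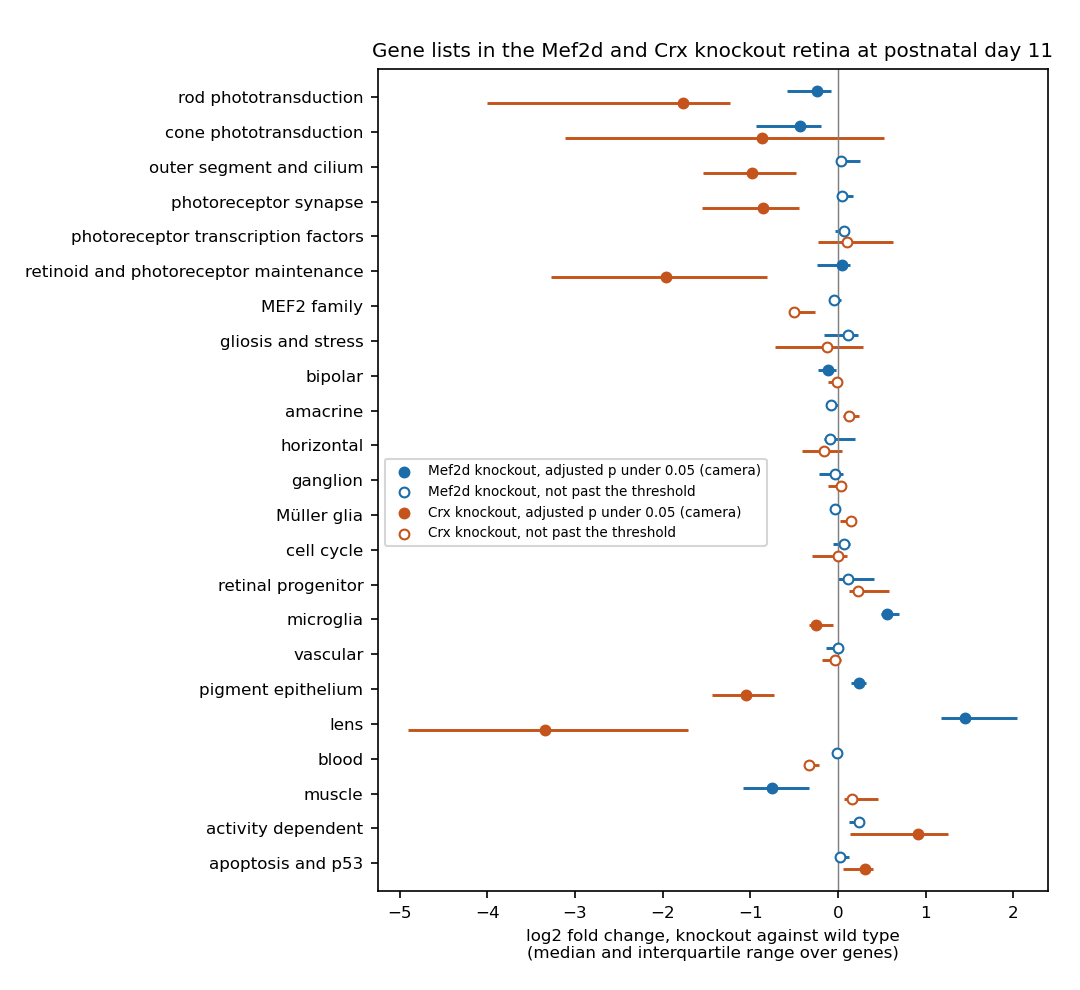
Median log2 fold change (horizontal axis) of the genes of each list, knockout against wild type, with the interquartile range over genes as a bar; blue is the Mef2d knockout, orange the Crx knockout, and filled circles mark a camera adjusted p under 0.05. The rod list lies at −0.24 in the Mef2d knockout and −1.77 in the Crx knockout, and the microglia list at 0.55 and −0.25.

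The Crx knockout retina held far less of the rod and cone photopigment transcripts than wild type. Medium-wavelength opsin Opn1mw dropped from 13.96 ± 2.73 to 0.0538 ± 0.0046 (SD, n = 2), short-wavelength opsin Opn1sw from 23.8 ± 0.19 to 0.554 ± 0.0182, and rod transducin Gnat1, which relays the rhodopsin signal, from 366 ± 73.3 to 5.03 ± 0.000495. Rhodopsin was at 760 and 959 in the wild types and at 65.7 and 18.0 in the knockouts, a log2 change of −4.63 ± 0.55 (limma adjusted p = 0.00269). Several genes with little transcript in wild type rose, among them the keratin gene Krt73, from 0.003 ± 0.00255 to 11.4 ± 3.95. Of 15601 genes tested with limma, 1283 rose and 1440 fell at an adjusted p below 0.05, and 272 of the rises and 542 of the falls reached 2-fold. The median-of-ratios scaling gave 1038 up and 1723 down. Leaving out a wild-type library lowered the number of calls to 1191 (without wild type 3) or 1003 (without wild type 4).

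Of the 7 largest falls among genes with a mean density of at least 1.65, 5 belonged to the phototransduction and outer segment lists. The log2 change was −7.63 ± 0.15 for Opn1mw (GeneID 14539, chrX:71372805–71396095, mm9), −6.48 ± 0.16 for Guca1b, −6.36 ± 0.31 for Pdzph1, −6.17 ± 0.15 for Gnat1 (GeneID 14685, chr9:107576805–107581923), −5.95 ± 0.25 for the predicted gene EG665234, −5.84 ± 0.14 for the calcium sensor Rcvrn (GeneID 19674, chr11:67500799–67516835) and −5.83 ± 0.31 for Fscn2, with limma adjusted p between 8.10e-06 and 0.000137 (n = 2 per group). The 7 largest rises above the same mean density of 1.65 were Krt73 (GeneID 223915, chr15:101623739–101632763) by 9.19 ± 0.25, the connexin-related Gje1 by 6.31 ± 0.22, the homeobox gene Obox6 by 6.02 ± 0.18, the zinc finger gene Insm2 by 5.69 ± 0.21, A930009A15Rik by 5.28 ± 0.15, the glycosyltransferase gene B3gnt2 by 3.72 ± 0.14 and the fatty acid binding protein gene Fabp7 by 3.58 ± 0.10, with limma adjusted p between 1.88e-05 and 4.88e-05. Obox6 (GeneID 252830) lies at chr7:16418599–16425028 in mm9, close to Crx itself and on the same strand. Whether the targeted Crx locus alters Obox6 locally was not tested.

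Rod genes fell almost without exception in the Crx knockout. In the rod list 18 of 19 genes fell and 0 rose, also when adjusted over the list alone (median log2 −1.77, camera adjusted p = 7.91e-20; adjusted p = 0.457 with an estimated correlation). The outer segment and cilium list had 14 falls and 0 rises of 19, or 14 and 1 when adjusted over the list alone (median −0.98, camera adjusted p = 9.68e-11; adjusted p = 0.391 with an estimated correlation). Its falls included the retinoid transporter Abca4 (−1.58 ± 0.11) and the ciliary protein gene Fam161a (−1.66 ± 0.09). The synapse list had 12 falls and 0 rises of 15, or 12 and 1 when adjusted over the list alone (median −0.85, camera adjusted p = 2.17e-09; adjusted p = 0.457 with an estimated correlation). The ribbon synapse calcium sensor Cabp4 (−3.398 ± 0.18) and complexin Cplx4 (−1.72 ± 0.09) fell. The retinoid and maintenance list had 11 falls and 0 rises of 14, or 12 and 0 when adjusted over the list alone (median −1.97, camera adjusted p = 6.26e-12; adjusted p = 0.457 with an estimated correlation), with the retinol dehydrogenase Rdh12 at −3.39 ± 0.23, the cone viability factor gene Nxnl1 at −2.94 ± 0.11 and Kcnv2 at −2.03 ± 0.10.

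Cone genes split. Of 13, 5 fell and 4 rose, or 8 and 4 when adjusted over the list alone (median log2 −0.87, camera adjusted p = 0.0196; adjusted p = 0.457 with an estimated correlation), and the list was not called under median-of-ratios scaling (camera adjusted p = 0.0783). Both opsins and Arr3 (−3.11 ± 0.09) fell. The cone transducin subunits Gngt2 (from 23.8 ± 0.313 to 120 ± 2.44, log2 2.33 ± 0.09) and Gnb3 (0.52 ± 0.11), the cone channel subunit Cngb3 (1.16 ± 0.10) and Ccdc136 (2.66 ± 0.14) rose, with limma adjusted p from 6.54e-05 to 0.0256. These 4 genes, and rhodopsin, Nrl and Otx2, were singled out after their values were seen. The Gnb3 call was lost in limma without wild type 3 (adjusted p = 0.179) or wild type 4 (0.207). Pde6h stood at 35.9 and 40.6 in the wild types and at 0.0249 and 5.02 in the 2 knockouts, and with that spread did not pass the threshold (limma adjusted p = 0.0769).

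Photoreceptor transcription factors went both ways in the Crx knockout. Of 14, 6 rose and 2 fell, or 6 and 3 when adjusted over the list alone (camera adjusted p = 0.549). The cone nuclear receptor Rxrg rose by 3.31 ± 0.11, Samd7 by 1.97 ± 0.11 and Otx2, the homeobox factor that acts upstream of Crx, by 0.99 ± 0.09. Esrrb (−4.87 ± 0.26) and the rod factor Nrl (−1.36 ± 0.13) fell. Mef2a (−0.03), Mef2b (−0.50) and Mef2c (−0.50) did not pass the threshold and the MEF2 list was not called (camera adjusted p = 0.298). Mef2b stood at 0.182 and 0.577 in wild types 3 and 4. Without wild type 3 its log2 change was −1.29 (limma adjusted p = 0.0136) and the MEF2 list was called down (median −0.70, camera adjusted p = 0.0310).

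**Figure D2:**
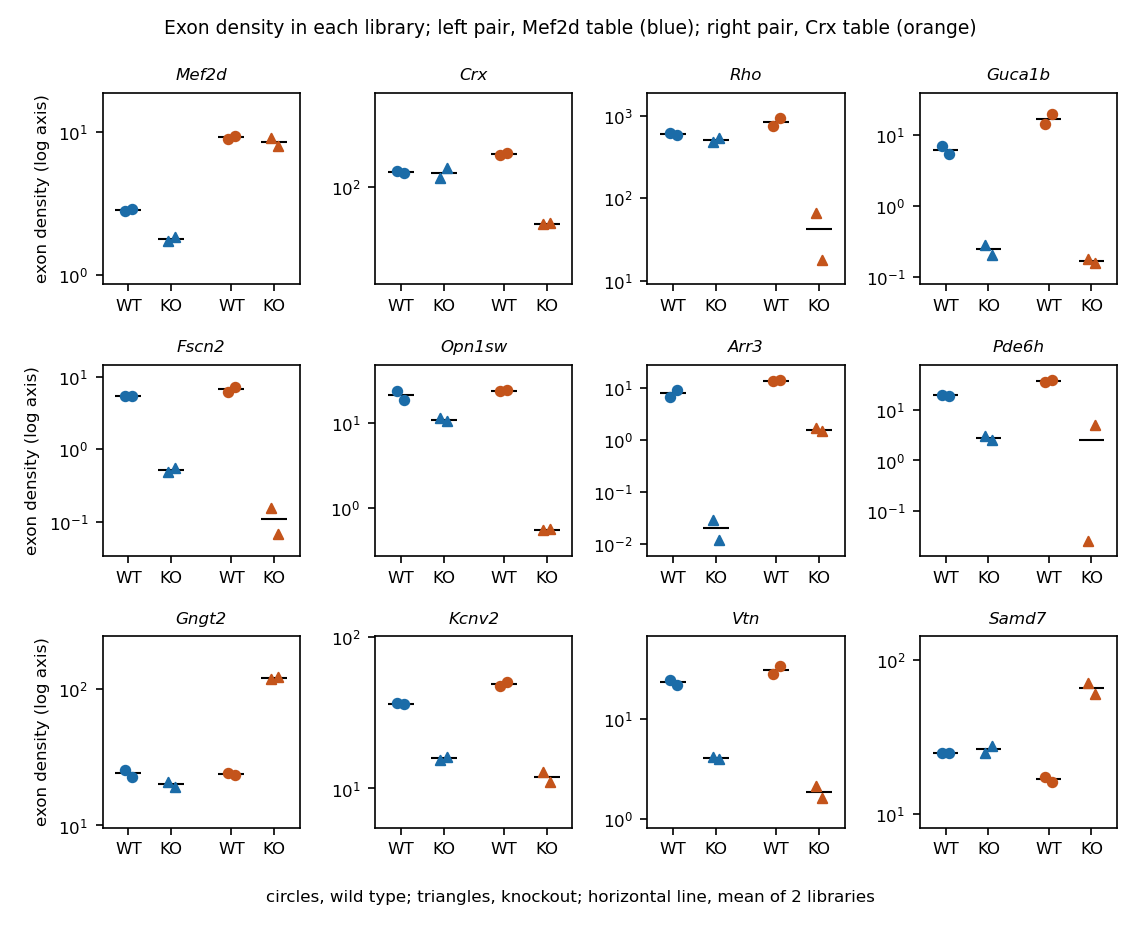
Exon density (vertical axis, log scale) of 12 genes in each of the 8 libraries; circles are wild types, triangles knockouts, horizontal lines the mean of 2 libraries, blue the Mef2d table and orange the Crx table; whether both tables were scaled alike is not given. Arr3 drops to 0.0209 in the Mef2d knockout and 1.57 in the Crx knockout, while Gngt2 reaches 120 in the Crx knockout.

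Some genes of acute neuronal activity and of apoptosis rose in the Crx knockout. Of 12 activity-dependent genes 5 rose, 0 fell and 7 did not pass, or 8 and 0 when adjusted over the list alone (median log2 0.91, camera adjusted p = 0.0196; adjusted p = 0.614 with an estimated correlation and 0.129 with fry). The immediate early factor Egr1 rose by 1.56 ± 0.15. Its mean density was 0.749 in these wild types and 0.169 in those of the Mef2d table, below the 0.570 of the Mef2d knockouts. The same scaling of the tables is not given. The camera call was lost without Crx knockout 2 (adjusted p = 0.0522). Of 11 apoptosis and p53 genes 3 rose, 0 fell and 8 did not pass, or 5 and 0 when adjusted over the list alone (median 0.31, camera adjusted p = 0.0289; adjusted p = 0.457 with an estimated correlation), led by Trp53, the gene of p53, at 1.04 ± 0.09. That call was lost in camera without wild type 4 (adjusted p = 0.0533) and without Crx knockout 2 (0.0747).

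Lens and pigment epithelium transcripts were lower in the Crx knockout. Of 15 lens genes 13 fell and 0 rose, also when adjusted over the list alone (median log2 −3.34, camera adjusted p = 7.66e-12; adjusted p = 0.391 with an estimated correlation). The alpha crystallin Cryaa went from 0.756 ± 0.0412 to 0.0101 ± 0.00474, and Crygb, at a mean of 0.882 in wild type, was listed at 0 in both knockouts. The summed lens density was 5.34 and 10.5 in these wild types and 0.933 and 0.884 in the knockouts, against 0.999 and 0.892 in the wild types of the Mef2d table, for which the same scaling is not given. Of 12 pigment epithelium genes 10 fell and 0 rose, also when adjusted over the list alone (median −1.05, camera adjusted p = 1.27e-07; adjusted p = 0.457 with an estimated correlation), with the melanosome protein gene Pmel at −2.07 ± 0.11. The microglia list had a median of −0.25 with 0 of 15 genes past the threshold, also when adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.614 with an estimated correlation). That call was lost in camera without wild type 4 (adjusted p = 0.102) and without Crx knockout 2 (0.124).

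Inner retinal cell lists were not called in the Crx knockout with all 4 libraries. Camera adjusted p was 0.133 for retinal progenitor, 0.173 for gliosis (0.0215 without Crx knockout 1), 0.246 for blood, 0.249 for amacrine, 0.298 for muscle, 0.322 for bipolar, 0.322 for Müller glia, 0.437 for horizontal cell, 0.549 for vascular, 0.578 for cell cycle and 0.909 for ganglion cell genes. Over all genes tested and likewise when adjusted over the list alone, 1 amacrine, 1 ganglion cell and 1 muscle gene rose, 1 horizontal cell gene rose and 1 fell, 2 vascular genes rose and 1 fell, 2 cell cycle genes rose and 2 fell, and 0 bipolar, blood and MEF2 genes passed. The Müller glia and progenitor lists had 1 rise each, or 0 when adjusted over the list alone, and the gliosis list 1 rise and 2 falls, or 2 and 2 when adjusted over the list alone. Lcn2 of the gliosis list fell by 4.25 ± 0.23 from a wild-type density of 0.317, Calb1 fell by 0.89 ± 0.10 and the troponin gene Tnnc2 rose by 2.14 ± 0.22 from 0.0154. Smaller changes were those of Cebpd (0.64), Col4a2 (0.60), Mcm7 (0.50), Tfap2c (0.49), Pou4f1 (0.44), Apoe (0.42) and A2m (−0.99), with limma adjusted p from 0.0128 to 0.0454, and each of these lost its call without at least 1 of the 4 libraries. Vsx1 (−0.29), Hbb-b1 (−0.34) and Tyrobp (−0.47) did not pass the threshold (limma adjusted p = 0.112, 0.173 and 0.059), though Vsx1 (0.0476) and Tyrobp (0.0408) did with median-of-ratios scaling and Vsx1 also without Crx knockout 2 (0.0490).

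Genes that fell in the Mef2d knockout tended to fall in the Crx knockout as well. Of 292 genes down in the Mef2d knockout and tested in both tables, 158 were also down in the Crx knockout, against 27.9 for independent lists (odds ratio 12.4, 95% interval 9.74 to 15.9, Fisher exact adjusted p = 6.29e-84). Vtn, which encodes the matrix protein vitronectin, had log2 changes of −2.52 ± 0.08 and −4.05 ± 0.15 in the Mef2d and Crx knockouts, Guca1b −4.56 and −6.48, Grtp1 −1.43 ± 0.10 and −2.83 ± 0.10, the mitochondrial NAD kinase gene Nadk2 −1.19 ± 0.08 and −2.63 ± 0.09, and Arr3 −7.63 and −3.11. Up in both were 49 genes against 26.5 (odds ratio 2.04, Fisher exact adjusted p = 4.21e-05). Genes are not independent replicates, so these p values describe the lists and not a number of animals. The counts down and up in both were 96 and 21 without wild type 1 of the Mef2d table, 116 and 21 without its wild type 2, and 87 and 17 without a filter. Up in both were 29 genes without wild type 3 and 31 without wild type 4 of the Crx table.

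A further group went in opposite directions. Of 318 genes up in the Mef2d knockout, 116 were down in the Crx knockout, against 30.4 for independent lists (odds ratio 5.83, Fisher exact adjusted p = 1.83e-39). That count of 116 was 57 without wild type 1 and 65 without wild type 2 of the Mef2d table, 65 without wild type 4 of the Crx table, and 36 without a filter. The collagen gene Col5a3 had log2 changes of 1.38 ± 0.13 without Mef2d and −2.90 ± 0.20 without Crx, Cutal 1.09 ± 0.11 and −3.18 ± 0.24, and the urea cycle enzyme gene Asl 0.85 ± 0.08 and −1.20 ± 0.10. The reverse, down without Mef2d and up without Crx, held for 21 genes against 24.3 (Fisher exact adjusted p = 0.592); it held for 9 and 12 without wild types 1 and 2 of the Mef2d table, 8 and 13 without wild types 3 and 4 of the Crx table, and 7 without a filter. Across the 14891 genes tested in both, the fold changes had a Pearson r of 0.08 and a Spearman rho of −0.03, and across the 344 called in both, r was 0.37 and rho 0.27. Over all genes r was 0.0405 without wild type 4 of the Crx table, 0.0445 without Mef2d knockout 1 and 0.20 with the stricter filter.

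**Figure D3:**
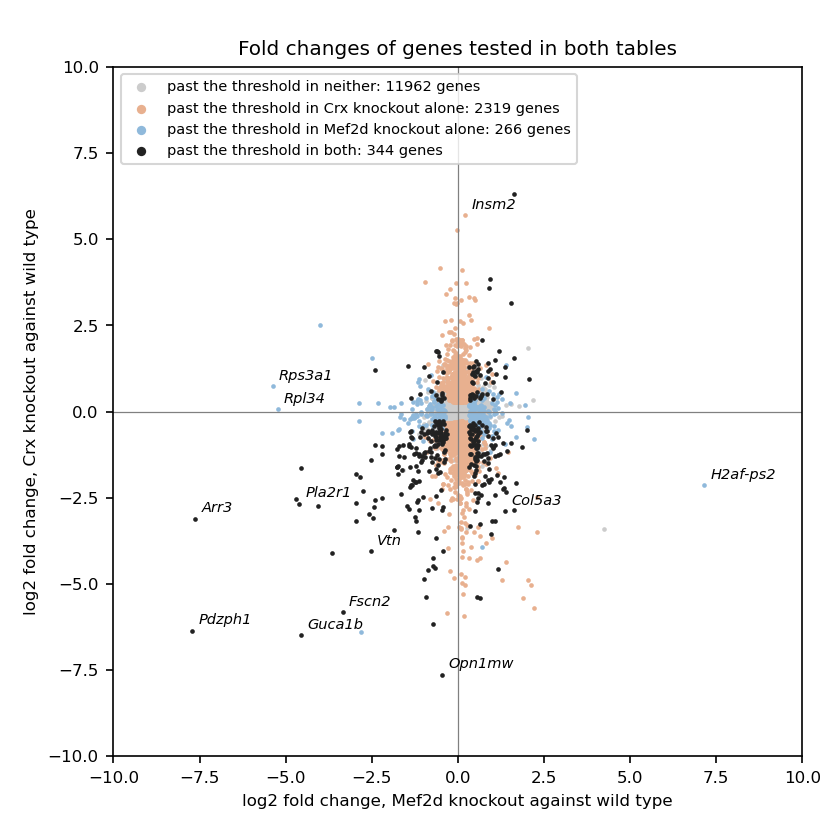
Log2 fold change of each of 14891 genes in the Mef2d knockout (horizontal axis) and the Crx knockout (vertical axis), each against its own wild types; black points passed the threshold in both tables (344 genes). The lower left quadrant holds Arr3, Guca1b, Pdzph1, Fscn2 and Vtn.

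The size of change differed between the knockouts for many genes. A joint limma fit called 2073 genes for the difference (757 higher and 1316 lower in the Crx knockout effect), including 371 of the 610 genes called in the Mef2d knockout and 82 of the 207 that changed in the same direction in both. Arr3 fell more without Mef2d than without Crx, by 4.52 ± 0.29 on the log2 scale (limma adjusted p = 1.95e-05). Guca1b (−1.92 ± 0.27), Vtn (−1.53 ± 0.19), Nadk2 (−1.44 ± 0.13) and Grtp1 (−1.40 ± 0.15) fell more without Crx, with limma adjusted p of 0.000112 to 0.00158. The largest differences were those of Gm5148 (6.51), Rps3a1 (6.13) and Insm2 (5.47) on the positive side and H2af-ps2 (−9.30), Crygb (−7.89) and Crygd (−7.31) on the negative side, where the crystallin genes Crygb and Crygd were listed at 0 in both Crx knockouts. Their limma adjusted p ran from 1.24e-05 to 0.0124. Gm5148 and Rps3a1 lie on chromosome 3, as does Mef2d. The Crx effects of Gm5148 (2.51, limma adjusted p = 0.181) and H2af-ps2 (−2.13, adjusted p = 0.251) did not pass the threshold; they were 0.59 and −0.17 without wild type 3, 4.42 and −4.09 without wild type 4, and that of Rps3a1 (0.75) was 0.27 without wild type 3 and 1.23 without wild type 4. The Mef2d effects of Crygb (2.20) and Crygd (1.89) were 4.17 and 4.01 without Mef2d knockout 1, and 0.23 and −0.23 without Mef2d knockout 2. The count of differing genes was 1322 without wild type 1 and 1352 without wild type 2 of the Mef2d table, and 1371 without wild type 4 of the Crx table.

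Genes past the threshold in the Mef2d knockout were more frequent on chromosome 3, where Mef2d lies. Of 740 tested genes there, 51 (6.89%) passed, against 569 of 14322 (3.97%) elsewhere (odds ratio 1.79, 95% interval 1.30 to 2.41, Fisher exact adjusted p = 0.00227). This comparison was chosen after the calls were seen. On chromosome 7, which holds Crx, 175 of 1185 genes (14.8%) passed in the Crx knockout, against 17.7% elsewhere (odds ratio 0.81, 95% interval 0.68 to 0.955, Fisher exact adjusted p = 0.0288).

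**Figure D4:**
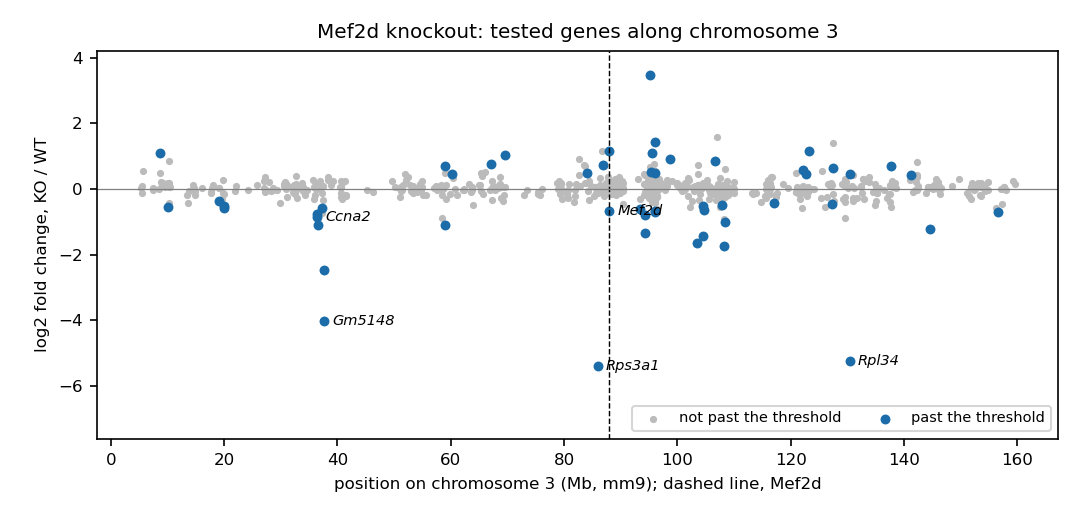
Log2 fold change in the Mef2d knockout (vertical axis) of the tested genes of chromosome 3 by position (horizontal axis, Mb, mm9); blue points passed the threshold and the dashed line marks Mef2d. Rps3a1 (−5.38) and Rpl34 (−5.23) are the lowest points.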

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

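The tests on chromosomes, on lens and pigment epithelium, on the markers of other retinal cells and on the spread within the rod and cone lists in the Mef2d knockout were chosen after the result was seen. The bound on the interquartile range of rod, outer segment and synapse genes was set before, as was that on the distance between the medians of other retinal cells. For the spread within the rod and cone lists a stricter bound, a majority of each list, was tried first and was met with all libraries but not with each left out.

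For 2073 genes the joint limma fit called a difference between the 2 knockouts, which cannot be told apart from an effect of the table. The named ones were Gm5148 (6.51) and Rps3a1 (6.13), both on chromosome 3, Insm2 (5.47), H2af-ps2 (−9.30), Crygb (−7.89) and Crygd (−7.31), as the log2 change in the Crx knockout minus that in the Mef2d knockout. Several of them hang on single libraries: the Crx effects of Gm5148 (2.51) and H2af-ps2 (−2.13) were 0.59 and −0.17 without wild type 3 and 4.42 and −4.09 without wild type 4, and the Mef2d effects of Crygb (2.20) and Crygd (1.89) were 4.17 and 4.01 without Mef2d knockout 1 and 0.23 and −0.23 without Mef2d knockout 2. Ribosomal RNA repeats, which no comparison used, took 14.9% of the density in Crx knockout 1 and 14.9% in Crx knockout 2, above the 14.1% and 12.5% of their wild types.

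Most rod, outer segment and synapse genes fell in the Crx knockout, and in the Mef2d knockout a subset of rod and cone genes fell; a lower share of photoreceptor cells is a candidate explanation that would lower them by a common amount. In the Crx knockout the medians of the bipolar, amacrine, Müller glia and ganglion lists ran from −0.012 to 0.15. They lay 0.16 apart, within the bound set beforehand, so that measure did not argue against a lower share, though the lowest median did not rise. The fold changes of 53 rod, outer segment and synapse genes had an interquartile range of 1.13 (1.03 to 1.22 with single libraries left out). This exceeded the bound of 1 set beforehand, which argues against a lower share as the whole cause. Whether each of these genes is confined to photoreceptors was not tested. In the Mef2d knockout these genes did not meet that bound (0.37), but 10 of 19 rod genes (8 to 9 with single libraries left out) and 9 of 13 cone genes (5 to 8) had a 95% interval that left out the median of their list, where a common change gives 5% by chance and the bipolar list gave 5 of 18 and the amacrine, Müller glia and ganglion lists 1, 0 and 0 of 13. That argues against a lower share of rods or cones as the whole cause of these falls, though the 5% assumes genes that vary independently. Among rod genes Pde6b (0.21 ± 0.08) stood beside Sag (−1.35 ± 0.15), and among cone genes Pde6c (−0.05 ± 0.07) beside Pde6h (−2.82 ± 0.10). All 13 cone genes had a log2 change below 0 (highest −0.03). The highest median of the bipolar, amacrine, Müller glia and ganglion lists, −0.033 (0.05 without wild type 1), lay too near 0 to decide. A partial loss of cells stays open in the Crx knockout and in the Mef2d knockout. A direct or indirect effect of either missing factor was not tested and stays open as well.

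Calls in the Mef2d knockout were more frequent on the chromosome of Mef2d (odds ratio 1.79). A different sequence background around the targeted gene may account for part of them. The same chromosome gave 0.91 in the Crx knockout, which does not measure the spread among chromosomes in the Mef2d knockout. There the share of calls over 20 chromosomes ran from 2.09% on chromosome X through 5.33% on chromosome 4 to 6.89% on chromosome 3. The window of 10 Mb around Mef2d was not enriched past the threshold (1.51, 95% interval 0.81 to 2.62), which leaves the extent of such a background open. That window gave 0.52 (0.33 to 0.80) in the Crx knockout, in which no gene there was targeted. In the Crx knockout the chromosome of Crx gave 0.81 (95% interval 0.68 to 0.955). The window of 10 Mb around Crx, where Obox6 (6.02) lies, gave 0.82 (0.50 to 1.29). The share of calls in that knockout ran from 13.8% on chromosome 13 to 21.6% on chromosome 4, which hold no targeted gene. A ratio below 1 therefore cannot decide, and a background around Crx or over its chromosome stays open. Comparing a chromosome with the rest also cannot detect a background shared by all chromosomes. An effect of MEF2D on genes of chromosome 3 was not tested.

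Lens and pigment epithelium transcripts were lower in the Crx knockout. The lens list median of the Crx-table wild types lay at least 3.25 (log2) above that of the Mef2d-table wild types, which share the genotype, against a shift of 0.15 for the median of all genes, though whether the tables were scaled alike is not given. Within 1 genotype and table, Mef2d knockout 2 lay 3.27 above Mef2d knockout 1. These values are in line with different amounts of lens tissue carried into the samples, and an effect of genotype on lens genes was not tested apart from it. For pigment epithelium, carried-over tissue and an effect of the knockout cannot be told apart: the genes fell by similar amounts (interquartile range 0.71), and the list median was 0.35, 0.36, 0.35 and 0.43 in the 4 wild types of both tables against −0.44 and −0.64 in the Crx knockouts, so unlike lens it differed little between wild types, which goes against carry-over that varies at random, though less tissue carried along with the knockout retinae stays open.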

How the results depend on the processing

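The alternatives without a chromosome and with a mean density of at least 1 were chosen after the result was seen; the others were planned. With counts of genes past the limma threshold as the measure, the Mef2d comparison (621) gave 271 without a filter, 278 without trend, 388 with at least 1.5-fold, and 291 to 721 with single libraries left out. The Crx comparison (2723) gave 1556 with at least 1.5-fold and 1003 to 2781 with single libraries left out. The lowest counts came without a wild-type library (291 and 364; 1191 and 1003), while without a knockout library they were 686 and 721 (Mef2d) and 2781 and 2102 (Crx); the cause of these changes was not tested. Added alternatives gave 555 and 2573 without the chromosome of the targeted gene, 776 and 2853 without the sex chromosomes, and 502 and 2166 at a mean density of at least 1. With an estimated correlation camera called 0 lists in the Mef2d comparison and 0 in the Crx comparison, and fry called 1 and 8; with single libraries left out camera called 6 to 12 and 7 to 11 (8 and 10 with all). Among named genes, left-out libraries ended a limma call in 15 (Mef2d) and 23 (Crx) cases and made one in 7 and 5, and the other settings ended 3 and 3 and made 13 and 4. The lens median in the Mef2d knockout (1.45) ranged from 0 without Mef2d knockout 2, with the camera test turned to down, to 3.26 without Mef2d knockout 1. Genes changed in the same direction in both knockouts (207) numbered 104 without a filter and 117 to 216 with single libraries left out, and genes with a difference of effect (2073) 1322 to 1905. The correlation of fold changes (0.08) was 0.20 with the stricter filter and 0.0405 to 0.109 with single libraries left out; the cause was not tested. The replicate numbers share only a number and a sex: same-sex deviations correlated at −0.04 (Mef2d) and 0.04 (Crx), and a replicate block gave 1070 calls for Mef2d and 2772 for Crx, with 79 genes up in both, 213 up without Mef2d and down without Crx, and 44 the reverse. Count models (edgeR, planned for the case of raw counts) were not run because the values are not counts. Low densities limit what can be seen: below the filter density, genes rest on few reads.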

Other observations

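All comparisons in this part were looked at after the results were seen.

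Y-linked transcripts were not at the same floor in all females. In female Mef2d knockout 2, Ddx3y, Kdm5d, Eif2s3y and Uty had 2.22% to 2.72% of the mean density of the males of that table, against 0.0401% to 0.220% in the wild-type female. In the Crx table the knockout female had 0.0796% to 0.164% and the wild-type female 0.0432% to 0.136%. Mef2d knockout 2 is also the library with the summed lens density of 5.18, against 1.06 in Mef2d knockout 1. Whether the Y-linked and lens values share a source was not tested.

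Replicates of the Crx knockout differed for some abundant photoreceptor genes. Pde6h was 0.0249 in one and 5.02 in the other, and rhodopsin 65.7 and 18.0, while Opn1sw was 0.541 and 0.567 and Crx 64.7 and 66.0.

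The wild types of the 2 tables, whose scaling is not given, differed in Mef2d (2.84 and 9.20) more than in Crx (119 and 146) or Otx2 (30.1 and 30.5). Mef2d was not alone in this. Gnat1 (101 and 366), Esrrb (2.86 and 9.50), Guca1b (6.21 and 16.8) and Egr1 (0.169 and 0.749) also differed, while Gngt2 (24.1 and 23.8) lay close. Rps3a1 stood at 13.7 and 1.35 and Rpl34 at 19.6 in the Mef2d-table wild types. Among genes abundant in most tissues, Gapdh had only 1.18, Ppia 0.313 and Tpt1 1.76 in the Mef2d-table wild types; all have many near-identical copies.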
